A study of Glycine max with 20 samples.

How the data were processed

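Leaf RNA of soybean (Glycine max) was measured by RNA sequencing in 20 libraries from 2 near-isogenic lines sampled at 5 times, with 2 biological replicates per line and time. Near-isogenic lines share most of their genome and differ around the selected locus and at whatever else was carried with it. The labels name the lines rag2 (susceptible to aphids) and Rag2 (resistant), and the times as uninfested leaves (0 h) and leaves 4, 8, 24 and 48 h after aphid infestation. Per the labels' protocols, total RNA was extracted with Trizol, mRNA libraries were made with an Illumina kit and barcoded, and sequencing was on a HiSeq 2000. The lane of each library and the growth conditions were not given in the sources used here.

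The authors deposited 1 table of raw read counts per gene model, with 1 column per library and no normalization. Per the submitters' processing notes, TopHat 1.4.1, HTSeq 0.5.3, edgeR and Cuffdiff 1.3.0 were used. The row names of the deposited table include the totals that HTSeq writes. The genome build, the annotation release and the strand setting of the counting were not given in the sources used here. Without a strand setting, reads of overlapping or antisense genes cannot be told apart. The total of reads aligned to several places is 0 in every library, so reads shared by near-identical copies were either removed before counting or not marked, and values of such copies are uncertain. The 5 rows that name no gene were left out of library sizes and tests. Of all reads in the deposited table, 2.79% to 7.46% overlapped no gene model and 1.43% to 1.86% were ambiguous between models.

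The columns of the deposited table call the lines W and BC. The hour and the replicate number in each column name match the labels, but neither the table nor the labels say which of W and BC is the resistant line. The lines are therefore called W and BC throughout, differences are given as BC minus W, and no direction is given relative to resistance. The design fixed beforehand had assumed that this direction would be known.

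The table holds 66210 gene models with names of the soybean Glyma series. None of them matched the RefSeq gene table at hand (Glycine_max_v4.0), which uses other identifiers, and the files pair them with no gene names. Gene functions are therefore not given, coordinates are not given, and the 29 gene lists fixed before the data were examined (defence, hormone, phenylpropanoid, photosynthesis, circadian clock, other tissues and others) could not be resolved, so none was tested. By the naming convention of these models, the digits before the letter g are the chromosome and the digits after it, called the locus number here, rise along the chromosome. Chromosome and order were taken from the names alone.

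From the counts, models with enough reads were kept with filterByExpr by group, which left 38918. Library sizes were scaled by TMM, and 1 model with 10 groups (line by time) was fitted to all 20 libraries with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust glmQLFit), so that the spread was estimated with 10 residual degrees of freedom. All adjusted p-values are Benjamini-Hochberg values over the models tested, with a threshold of 0.05 and no fold minimum, and all edgeR tests are two-sided. Standard errors of log2 fold changes were computed from the fold change and the F statistic. The comparisons were BC against W averaged over the 5 times, BC against W at each time, each later time against 0 h within each line, and a joint F test of whether the response differed between the lines at any time. Levels are given as CPM (counts scaled by library size), with TMM-scaled library sizes. Where a line or group had 1 to 3 reads of a model, the ratio of reads per scaled library size is given with an exact 95% interval, and where it had none, the fold is a lower bound against 3 reads summed over the group. Such intervals and bounds cover counting error only.

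Calls of the averaged line comparison were counted per chromosome with a one-sided Fisher's exact test, adjusted over the 20 chromosomes. They were also counted in sliding windows of 50 consecutive tested models. A window was taken as full where it held more calls than the 95th percentile of the fullest window in 1000 random placements of the calls. Overlapping full windows were joined into regions, and each region was trimmed to begin and end at a called model. The window rule was set after the calls had been seen.

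The total over gene models ranged from 7558768 to 38227436 reads per library. The biological coefficient of variation was 0.285. The test was checked on counts simulated from the real means and library sizes with 100 models changed by 2-fold and 100 by 4-fold. The changed models all had an average log2 CPM of at least 1, so recovery among models with fewer reads was not measured. Each model had the same spread in all libraries, so the larger replicate differences of the BC 0 h group were not simulated. For the averaged line comparison (38460 models tested) it recovered 78.0% of 2-fold and 99.0% of 4-fold changes, with 4.32% false calls. For 8 h against 0 h in W (38453 models tested) it recovered 6% of 2-fold and 72.0% of 4-fold changes, with 2.5% false calls, so a 2-fold change was mostly out of reach there. Time comparisons in BC, line comparisons at a single time and the tests of a difference of responses were not simulated.

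Models named in the text were chosen by a rule fixed at the same stage as the gene lists. Since no table names the models, at most 2 that rose and 2 that fell are named per comparison. They are those with the largest log2 fold change past the threshold with an average log2 CPM of at least 1. For the averaged line comparison the sign had to be the same at all 5 times. For a time comparison both libraries of either group had to lie above both of the other.

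Alternatives fixed beforehand were DESeq2 size factors, no low-count filter, the tests of DESeq2 1.42.0, the replicate number as a block, a fit to only the 2 groups compared, and leaving out each library in turn, where the library left alone in its group is assumed to vary like the other groups. For the joint test, DESeq2's likelihood ratio test took the place of its Wald test. Thinning all libraries to the smallest total, limma 3.58.1 voom with library weights, and DESeq2's likelihood ratio test without each library in turn were added after the data were seen. The series design text calls the replicates biological, but the labels do not say what was pooled in each, so p-values measure the spread between these samples.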

Results

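The 20 libraries fell into 10 groups of 2, from 2 near-isogenic soybean lines called W and BC in the count table. Each line was sampled uninfested (0 h) and at 4, 8, 24 and 48 h after aphids were placed on the leaves. The soybean aphid is a phloem-feeding insect, and the lines were named for Rag2, a locus of resistance to it. There were no uninfested libraries at the later times, so time after infestation and time of sampling were a single factor. In W, replicates 1 and 2 held these numbers of reads in gene models: 24316970 and 34719102 at 0 h, 25896069 and 25994150 at 4 h, 9607642 and 15794574 at 8 h, 18076423 and 21069344 at 24 h, and 14647987 and 8809997 at 48 h. In BC they held 15185425 and 7558768 at 0 h, 14431627 and 9957702 at 4 h, 13915860 and 17725967 at 8 h, 29758817 and 38227436 at 24 h, and 12426112 and 7692936 at 48 h. Between 41702 and 47700 gene models had at least 1 read in a library.

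Replicates differed by more than counting noise in every group, with a chi-square per degree of freedom between 5.70 and 86.9, so no pair of replicates was a single library deposited again. The correlation of log2 CPM across gene models between replicates was lowest in the BC 0 h group, at 0.914, and highest in the BC 48 h group, at 0.973. The median absolute log2 difference between replicates was 0.61 in the BC 0 h group and lay between 0.22 and 0.39 in the other groups. Replicate 2 of the BC 0 h group had the lowest mean correlation with the other 19 libraries, 0.893, and the highest share of reads outside gene models, 7.46%, where the next library had 4.87%. The first principal component, with 23.7% of the variance, ran from -116 in replicate 2 of the BC 8 h group to 77.0 in replicate 2 of the BC 0 h group. The replicates of the BC 4 h group lay at -111 and 30.9 on it. On the third component, with 13.3% of the variance, replicate 2 of the BC 0 h group lay apart at -159. The next lowest there was replicate 2 of the BC 8 h group, at -35.5. The BC 0 h group is the baseline of each time comparison in BC and enters each comparison of the lines at 0 h.

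The first question was which transcripts differed between the lines whatever the time. Averaged over the 5 times, with 10 libraries per line, 83 of 38918 gene models differed, 53 higher and 30 lower in BC (edgeR, adjusted p below 0.05). Their median absolute log2 fold change was 1.61, and 62 of them differed by more than 2-fold. Of the 83, 77 kept the sign of their difference at all 5 times. Glyma13g25800.1 on chromosome 13 had 944 reads over the 10 BC libraries and 2 reads over the 10 W libraries, a ratio of 528 with a 95% counting interval of 146 to 4368 (5.68 ± 3.27 CPM in BC, SD, n = 10; edgeR adjusted p = 9.96e-04). It did not pass with library weights in limma voom. Glyma13g32470.1, also on chromosome 13, was at 14.1 ± 8.45 CPM in BC and 0.123 ± 0.153 CPM in W (SD, n = 10 each), a log2 fold change of 7.14 (6.38 at equal depth) with a standard error of 0.50 and an edgeR adjusted p of 5.26e-06. In the other direction, Glyma11g12980.1 had 1184 reads in W, at 5.92 ± 1.17 CPM, and 7 reads in BC, at 0.0656 ± 0.179 CPM (SD, n = 10 each; edgeR adjusted p = 6.60e-06). Of the 7 reads, 4 were in replicate 2 of the BC 0 h group, and the fitted log2 fold change moved from -8.19 to -9.23 without that library and to -6.81 in limma voom, so its size is uncertain. Glyma06g44010.1 was at 17.0 ± 3.13 CPM in W and 1.01 ± 0.503 CPM in BC (SD, n = 10 each), a log2 fold change of -4.15 with a standard error of 0.15 (edgeR adjusted p = 4.43e-09). DESeq2 called 272 models, 190 higher and 82 lower in BC, among them all 83. Without replicate 1 of the BC 0 h group, which leaves the deviating replicate 2 as its only library, the count was 519, and without replicate 1 of the W 8 h group it was 143. Without replicate 2 of the BC 0 h group it was 77, of which 69 were among the 83.

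The differing models were unevenly spread over the genome. Chromosome 13 held 40 of the 82 calls that lie on the 20 chromosomes, or 1.48% of its 2694 tested models (odds ratio 12.9, one-sided Fisher's exact test, p = 8.02e-25, adjusted over 20 chromosomes p = 1.60e-23). The test counts models as independent, which neighbouring models need not be, so the size of its p-value is not to be taken literally. On that chromosome, 39 of the 40 calls lay between locus numbers 24470 and 36370, 28 of them higher and 11 lower in BC. These bounds are the first call and the last call but 1, so 1 call lay outside by definition, at locus number 44520. The stretch held 836 tested models, and 1858 tested models of the chromosome lay outside it. No other chromosome passed the threshold. Chromosome 6 came next with 11 calls of 2274 tested models (odds ratio 2.50, adjusted Fisher's exact p = 0.0826), and it passed without the low-count filter (adjusted p = 0.00515), with the replicate number as a block (0.0105) and with DESeq2 (4.13e-05). It also passed without replicate 2 of the W 0 h (0.0278), W 4 h (0.0398), BC 0 h (0.0153) or BC 4 h group (0.0104) and without replicate 1 of the W 48 h group (0.0172). Chromosome 13 passed under each alternative tried, with an adjusted p of at most 2.57e-11.

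On a finer scale, windows of 50 consecutive tested models marked 5 regions, 3 of them on chromosome 13. The densest region, between locus numbers 25050 and 27090 of chromosome 13, held 19 calls among 124 tested models, 16 of them higher in BC, and its fullest window held 13 calls. Random placement of the calls gave at most 3 in the fullest window in 95% of placements. The other regions on chromosome 13 lay between locus numbers 29630 and 30140, with 4 calls of 37 tested, and between 32380 and 33160, with 7 calls of 56. Outside that chromosome, a region of chromosome 2 between locus numbers 32070 and 34490 held 4 calls of 34 tested models, and a region of chromosome 6 between 46800 and 47760 held 6 of 64. Together the 5 regions held 40 of the 82 calls in 0.812% of the tested models, and 12.7% of their models were called against 0.109% elsewhere. The regions were drawn around these same calls, so a higher share inside than elsewhere follows from the rule. Calls inside the regions were 25 higher and 15 lower in BC, and those outside 27 higher and 15 lower.

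**Figure D1:**
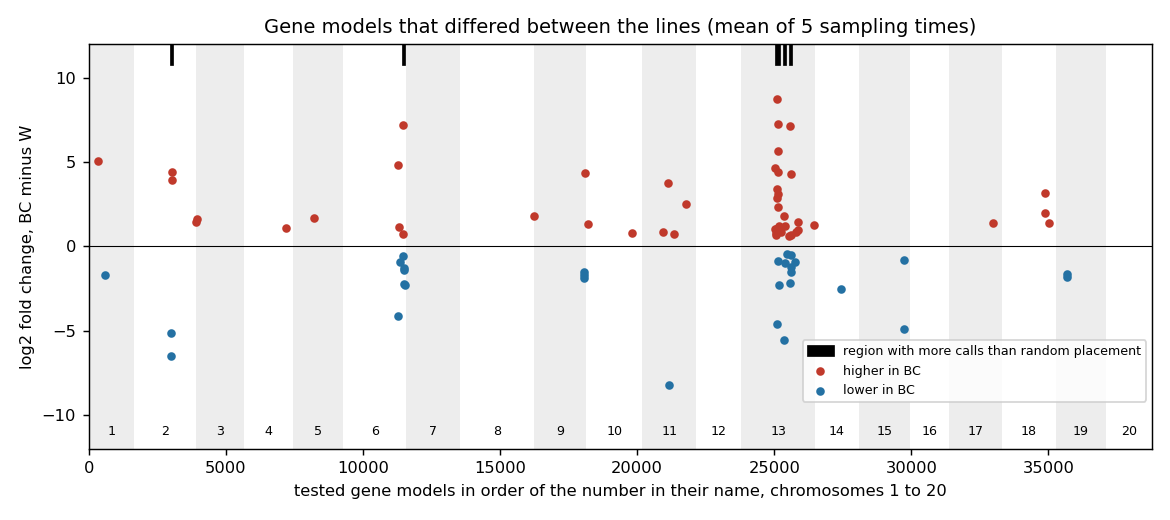
Log2 fold change (BC minus W, mean over 5 times) of the gene models past an adjusted p of 0.05 on chromosomes 1 to 20, plotted against the order of tested models by name; red points are higher and blue points lower in BC, grey bands mark every other chromosome, and black bars at the top mark the 5 regions. The densest stretch of points is on chromosome 13, which holds 40 of the 82 points, and points lie on both sides of 0.

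At single times, with 2 libraries per line, the lines differed in 7 gene models at 0 h, 12 at 4 h, 10 at 8 h, 12 at 24 h and 6 at 48 h (edgeR). In all, 17 models were called at 1 time or more and 4 at each of the 5 times. All calls except 1 at 8 h were among the 83 of the averaged comparison, which includes the same libraries. The same models led at several times. Glyma06g43880.1 was higher in BC at each time, by a log2 fold change between 4.46 at 8 h (standard error 0.51, edgeR adjusted p = 0.00334) and 5.37 at 0 h (standard error 0.51, edgeR adjusted p = 6.59e-04). In replicates 1 and 2 of the BC 0 h group it was at 53.1 and 21.9 CPM, so its size at 0 h is uncertain. Glyma06g44010.1 was lower in BC at each time, by a log2 fold change between -3.64 at 0 h (standard error 0.34, edgeR adjusted p = 6.59e-04) and -4.78 at 4 h (standard error 0.35, edgeR adjusted p = 6.53e-05). Its level in replicates 1 and 2 of the BC 0 h group was 0.872 and 2.29 CPM, so the size at 0 h is uncertain here too. Glyma11g12980.1 had no read in BC at 4 h and 8 h, where it was at 5.97 ± 1.98 and 5.38 ± 0.930 CPM in W (SD, n = 2), at least 50.4-fold and 66.3-fold lower in BC. Glyma02g34490.1 had no read in W at 48 h and 4.47 ± 0.0768 CPM in BC (SD, n = 2), at least 29.9-fold higher in BC. It was not absent from W at the other times. Its means at 0, 4, 8 and 24 h were 0.482, 0.831, 0.415 and 0.498 CPM in W, against 3.57, 5.63, 4.80 and 5.44 CPM in BC. These counts depended on single libraries and on the fit. At 0 h the count was 3 without replicate 1 of W and 7785 and 8 without replicates 1 and 2 of BC. At 4 h it was 3 and 2 without replicates 1 and 2 of W and 4 without either of BC. At 8 h it was 2 without replicate 2 of W, and 21 and 4 without replicates 1 and 2 of BC. At 24 h it was 2 without replicate 2 of W and 3 without either replicate of BC. At 48 h it was 1 without either replicate of W, and 0 (2611 at an unadjusted p below 0.05) and 3 without replicates 1 and 2 of BC. With library weights in limma voom the count was 1 at 0 h and 71 at 48 h. Fitted to only the 4 libraries compared, edgeR called 0 models at 0, 4, 8 and 24 h and 55 at 48 h, against unadjusted p below 0.05 for 1721, 1201, 5012, 2613 and 6664 models in these fits, and DESeq2 called 211, 26, 146, 23 and 78.

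The second question was how leaf transcripts changed after aphids were placed on each line. In W, edgeR called 309 gene models against 0 h at 4 h (155 higher, 154 lower) and 594 at 8 h (268 higher, 326 lower), then 0 at 24 h and 30 at 48 h (2 higher, 28 lower). The median absolute log2 fold change of the calls was 2.04 at 4 h and 1.88 at 8 h. At 4 h Glyma10g42470.1 rose from 1.11 ± 0.483 to 21.3 ± 15.9 CPM (SD, n = 2; log2 fold change 4.24, standard error 0.75, edgeR adjusted p = 0.0172) and Glyma11g00550.1 from 1.81 ± 0.382 to 30.3 ± 19.3 CPM. Glyma09g08330.1 fell from 11.0 ± 5.39 to 0.123 ± 0.0756 CPM and Glyma05g35940.1 from 6.08 ± 0.587 to 0.185 ± 0.113 CPM (SD, n = 2; edgeR adjusted p = 0.0224 and 0.00808). In BC the means of these models moved the same way from 0 h to 4 h. Glyma10g42470.1 went from 0.325 to 6.06 CPM and Glyma11g00550.1 from 1.62 to 26.6 CPM. Glyma09g08330.1 went from 3.19 to 0.867 CPM and Glyma05g35940.1 from 2.52 to 0.940 CPM. At 8 h Glyma09g00950.1 rose from 0.975 ± 1.34 to 48.7 ± 9.04 CPM and Glyma17g36060.1 from 0.624 ± 0.803 to 30.6 ± 1.29 CPM (SD, n = 2; edgeR adjusted p = 0.0211 and 0.0188). Glyma03g37490.1 fell from 6.57 ± 0.926 to 0.178 ± 0.0958 CPM and Glyma18g01720.1 from 6.62 ± 2.26 to 0.373 ± 0.0937 CPM (SD, n = 2; edgeR adjusted p = 0.00114 and 0.00179). From 0 h to 8 h the means of these models moved the same way in BC. Glyma09g00950.1 went from 2.65 to 40.8 CPM and Glyma17g36060.1 from 1.86 to 27.4 CPM. Glyma03g37490.1 went from 9.50 to 0.202 CPM and Glyma18g01720.1 from 5.56 to 0.516 CPM. At 48 h Glyma17g07270.1 fell from 23.1 ± 9.98 to 0.350 ± 0.312 CPM and Glyma06g10700.1 from 43.7 ± 12.8 to 2.29 ± 1.60 CPM, while Glyma01g32810.1 rose from 5.05 ± 0.192 to 15.1 ± 0.954 CPM (SD, n = 2; edgeR adjusted p = 0.0219, 0.0125 and 0.0125). Both falls were present in W before 48 h. Glyma17g07270.1 had means of 1.81, 1.32 and 3.07 CPM at 4, 8 and 24 h, and Glyma06g10700.1 of 2.18, 5.91 and 6.16 CPM. At 0 h in BC their means were 5.05 and 8.98 CPM, below those of W at 0 h.

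At 4, 8 and 48 h the counts in W fell when a library of the groups compared was left out. At 4 h they were 139 and 27 without replicates 1 and 2 of the 0 h group and 43 and 108 without replicates 1 and 2 of the 4 h group. The balance of directions moved with them, to 54 higher and 85 lower, 7 and 20, 26 and 17, and 80 and 28. At 8 h they were 261 and 213 without replicates 1 and 2 of the 0 h group and 244 and 151 without those of the 8 h group. The directions were then 123 higher and 138 lower, 77 and 136, 124 and 120, and 102 and 49. At 48 h the count was 0 without replicate 2 of the 0 h group and without replicate 1 or 2 of the 48 h group, with 2344, 1824 and 5048 models at an unadjusted p below 0.05. At 24 h, where edgeR called 0 models, 1504 had an unadjusted p below 0.05, limma with library weights called 7, DESeq2 called 58, and leaving out replicate 1 of the 24 h group gave 2. Fitted to only the 4 libraries compared, edgeR called 0 at 4 h (3626 at an unadjusted p below 0.05), 3 at 48 h, and 728 at 8 h, of which 426 were among the 594. DESeq2 called 730, 1205 and 479 models at 4, 8 and 48 h, and limma with library weights 547, 1131 and 93.

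In BC, edgeR called 32 gene models against 0 h at 4 h (17 higher, 15 lower), 1381 at 8 h (495 higher, 886 lower), and 0 at 24 h and 48 h. At 4 h Glyma13g43800.1 rose from 2.96 ± 1.77 to 56.9 ± 53.5 CPM and Glyma03g39200.1 from 11.8 ± 4.08 to 74.1 ± 14.9 CPM (SD, n = 2; edgeR adjusted p = 0.0365 and 0.0200). Glyma09g37490.1 fell from 9.26 ± 5.29 to 0.350 ± 0.236 CPM at 4 h and to 0.174 ± 0.0681 CPM at 8 h (SD, n = 2; edgeR adjusted p = 0.0203 and 5.16e-04). Glyma03g42260.1, an abundant transcript, fell from 349 ± 106 to 38.8 ± 2.41 CPM at 4 h (SD, n = 2; edgeR adjusted p = 0.0305). In W the means of these models moved the same way from 0 h to 4 h. Glyma13g43800.1 went from 6.87 to 39.5 CPM and Glyma03g39200.1 from 8.54 to 65.3 CPM. Glyma09g37490.1 went from 3.05 to 0.128 CPM and Glyma03g42260.1 from 233 to 42.6 CPM. At 8 h Glyma03g37490.1, which had fallen in W, fell from 9.50 ± 4.14 to 0.202 ± 0.160 CPM (SD, n = 2; log2 fold change -5.63, standard error 0.63, edgeR adjusted p = 4.43e-04). Glyma17g36090.1 rose from 3 reads to 1019 reads at 8 h, a ratio of 184 with a 95% counting interval of 62.8 to 894, but its 2 libraries at 8 h lay far apart (22.8 ± 30.6 CPM, SD, n = 2; edgeR adjusted p = 0.0455). Glyma20g39150.1 rose from 2 reads to 226 reads, a ratio of 61.2 with a 95% counting interval of 16.8 to 509 (5.94 ± 0.345 CPM at 8 h, SD, n = 2; edgeR adjusted p = 0.0201). Its rise was not particular to 8 h, with means in BC of 6.62, 8.38 and 10.2 CPM at 4, 24 and 48 h. In W its means were 3.16 CPM at 0 h and 3.81 CPM at 8 h, so the BC 0 h group was the low one. Those of Glyma17g36090.1 in W were 0.982 and 1.69 CPM.

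The counts in BC depended strongly on the 0 h group. Without its replicate 2, which lies apart from the other libraries, they were 0 at 4 h, 371 at 8 h (254 of them lower, and 328 among the 1381), and 0 at 24 h and 48 h, with 3126, 6001, 1890 and 1285 models at an unadjusted p below 0.05. Without its replicate 1 they were 8329, 8369, 8224 and 7214 at 4, 8, 24 and 48 h. Without replicates 1 and 2 of the 4 h group the 4 h count was 0 (3125 at an unadjusted p below 0.05) and 903, and without replicate 2 of the 8 h group the 8 h count was 236. The excess of lower calls at 8 h turned round in that fit (147 higher, 89 lower), and without replicate 1 of the 8 h group there were 486 higher and 509 lower. With library weights in limma voom the counts were 0 at 4 h (1954 at an unadjusted p below 0.05) and 46 at 8 h. In the edgeR fit to only the 4 libraries compared both were 0, with 2330 and 4210 models at an unadjusted p below 0.05. DESeq2 called 1895 at 4 h and 3841 at 8 h. At 24 h and 48 h, where edgeR called 0 models, 6831 and 4960 had an unadjusted p below 0.05 DESeq2 called 768 and 242, and limma with library weights called 0 at both.

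**Figure D2:**
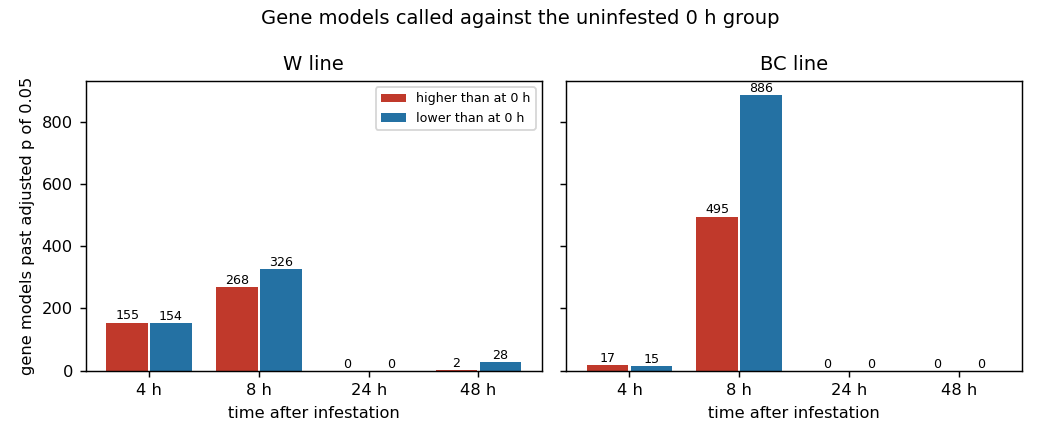
Number of gene models past an edgeR adjusted p of 0.05 at 4, 8, 24 and 48 h after infestation against the uninfested 0 h group of the same line, with W on the left and BC on the right; red bars count models higher and blue bars models lower than at 0 h. The counts peak at 8 h in both lines, with 268 and 326 in W and 495 and 886 in BC, and are 0 at 24 h in both.

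The responses of the lines can be set side by side because each line had its own 0 h libraries. At 8 h, 153 models were higher and 141 were lower in both lines, against 3.41 and 7.42 for independent lists of the same sizes, and 0 were called in opposite directions. At 4 h, 15 were higher and 9 lower in both, against 0.0677 and 0.0594 for independent lists. Of the 594 models called at 8 h in W, 89.7% had the same sign at 8 h in BC, and of the 1381 called in BC, 75.4% had the same sign in W. Over all tested models the sign was the same in 49.8%, and the fold changes at 8 h were uncorrelated across models (r = -0.0326, rho = -0.00873, across genes, which are not independent replicates).

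The models called at 8 h in either line were followed in the libraries of the other line, signed by the direction of the call. The 594 models called in W had a median change from the 0 h mean in BC of 0.49 ± 0.15 log2 units at 4 h, 1.12 ± 0.08 at 8 h, -0.10 ± 0.04 at 24 h and -0.02 ± 0.10 at 48 h (SD, n = 2 libraries). The 1381 models called in BC had a median change in W of 0.20 ± 0.29 at 4 h, 0.53 ± 0.13 at 8 h, -0.22 ± 0.16 at 24 h and -0.32 ± 0.03 at 48 h (SD, n = 2 libraries). In neither line did the median of a 24 h or 48 h library lie on the side of the 8 h change by more than 0.05 log2 units. These medians follow the calls of each line in the other line only. Within W, 25 of the 30 models called at 48 h were also called at 8 h, all 25 in the same direction. Both of these comparisons use the same 0 h libraries.

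**Figure D3:**
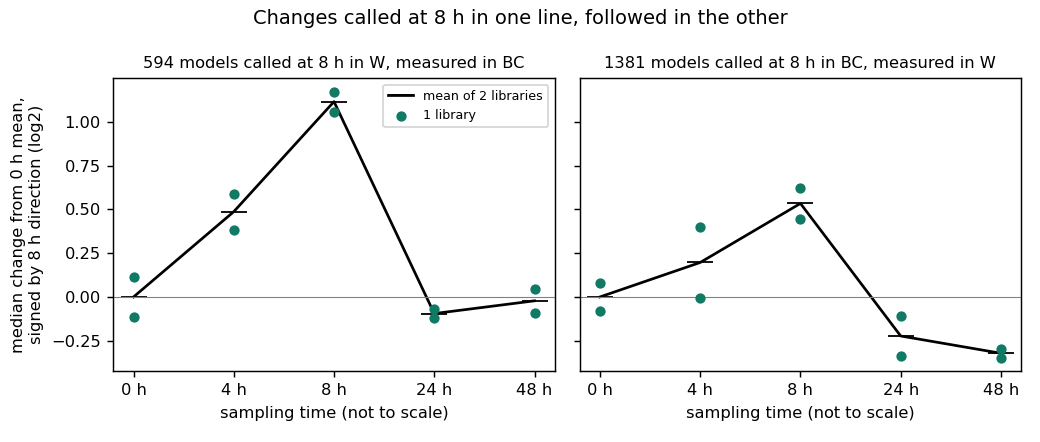
Median log2 change from the mean of the 0 h libraries, signed by the direction called at 8 h, for the 594 models called in W measured in BC (left) and the 1381 models called in BC measured in W (right), at 0, 4, 8, 24 and 48 h; points are single libraries and the line joins the means of 2. In both panels the highest value is at 8 h, with means of 1.12 and 0.53, and the 24 h and 48 h means are below 0.

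The last question was whether the response differed between the lines. The joint F test over the 4 later times called 0 gene models (edgeR, smallest adjusted p = 0.597), with 3121 at an unadjusted p below 0.05. How large a difference it could find was not simulated, so 0 calls do not show equal responses. Tested at each time, the difference of responses called 0 models at 4, 8, 24 and 48 h, with smallest edgeR adjusted p values of 0.274, 0.214, 0.370 and 0.236 and 4472, 6358, 4843 and 5686 models at an unadjusted p below 0.05. Limma with library weights called 0 in the joint test, and DESeq2's likelihood ratio test called 145 models. Without replicate 2 of the BC 0 h group it called 47, and without any other library 76 to 5209, the highest without replicate 1 of that group. In edgeR the count was 1801 without replicate 1 of that group and 4 without replicate 1 of the W 8 h group.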

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

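The DESeq2 fits without single libraries were chosen after the result was seen. The prediction that an outlying library hides responses was reworded after its values had been seen, so it counts as a test chosen afterwards. No group held the 4 libraries needed to look for an outlying value. None of the 19 responses named for a time comparison moved in opposite directions in the lines.

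A difference of response between the lines stood out because DESeq2's likelihood ratio test of the line by time interaction called 145 gene models where edgeR called 0 (3121 at an unadjusted p below 0.05) and limma with library weights 0. Without replicate 2 of the BC 0 h group DESeq2 called 47, of which 33 were among the 145, while leaving out any of the other 19 libraries left 76 to 5209 calls, so 0 of them left as few. The calls may therefore rest on this library more than on any other, although without replicate 1 of the W 0 h group 55 of the 145 were called. Whether the library also hides responses in BC by widening the spread stays open, since the fall from 1381 to 371 edgeR calls at 8 h without it had a counterpart in W, where leaving out replicate 1 or 2 of the 0 h group lowered 594 calls to 261 or 213. Differences in its harvest or preparation and a difference between the plants sampled stay open and were not tested.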

How the results depend on the processing

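The fits at equal depth, with library weights and of DESeq2 without single libraries were chosen after the data were seen. Directions of the named models held in each of the 533 recomputed values, while 152 of these lost the threshold. DESeq2's tests called 272 models for the averaged line comparison, 211, 26, 146, 23 and 78 for the lines at 0, 4, 8, 24 and 48 h, 730, 1205, 58 and 479 in W and 1895, 3841, 768 and 242 in BC at 4, 8, 24 and 48 h, and 145 for the difference of responses (47 without replicate 2 of the BC 0 h group). For each of these and the following differences the cause was not tested. Without the low-count filter the counts were 18, 16 and 15 for the lines at 0, 8 and 48 h, 57 at 48 h in W and 138 at 4 h in BC. Fitted to only the 2 groups compared, which leaves 2 residual degrees of freedom, they were 0 for the lines at 0, 4, 8 and 24 h and 55 at 48 h, 0 and 3 in W at 4 and 48 h, and 0 in BC at 4 and 8 h. Thinned to equal depth, they were 7 for the lines at 4 h and 7 at 24 h, and 64 at 4 h in BC. With library weights they were 1 and 71 for the lines at 0 and 48 h, 547, 1131, 7 and 93 in W at 4, 8, 24 and 48 h, and 0 and 46 in BC at 4 and 8 h. DESeq2 size factors moved no count by more than 1.5 times.

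With each library left out in turn, the averaged line comparison ran from 59 to 519. The lines ran from 3 to 7785 at 0 h, 2 to 4 at 4 h, 2 to 21 at 8 h, 2 to 9 at 24 h and 0 to 3 at 48 h. In W the counts ran from 27 to 139 at 4 h, 151 to 261 at 8 h, 0 to 2 at 24 h and 0 to 23 at 48 h, and in BC from 0 to 8329, 236 to 8369, 0 to 8224 and 0 to 7214. The difference of responses ran from 0 to 1801. With DESeq2 it was, without replicates 1 and 2 in turn, 76 and 124 for W at 0 h, 355 and 420 at 4 h, 220 and 160 at 8 h, 187 and 169 at 24 h, and 78 and 165 at 48 h. For BC it was 5209 and 47 at 0 h, 444 and 1225 at 4 h, 739 and 128 at 8 h, 120 and 90 at 24 h, and 88 and 82 at 48 h. The upper ends in BC, at 0 h and for the difference of responses came without replicate 1 of the BC 0 h group. The number of chromosomes past the threshold was 1 or 2, the second being chromosome 6, and it was 2 without the filter, with the block and with DESeq2.

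The replicate number was also fitted as a block. The replicate differences of the 10 groups correlated between -0.478 and 0.498 over 45 pairs of groups, with 15 pairs above 0.1 and 10 below -0.1. The numbers therefore did not pair the libraries alike in all groups. A pairing shared by some of the groups cannot be excluded by these values. The replicate block moved the line comparison at 8 h from 10 to 5 and 4 h in BC from 32 to 86, and the averaged line comparison from 83 to 74. The gene list tests were not run, since the names could not be resolved. At equal depth the averaged line comparison gave 59 calls, 55 of them among the 83 (3024 models at an unadjusted p below 0.05, against 3546).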

Other observations

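The tests of the clusters, the gaps along the principal component, the fit at equal depth and the test of other models at 24 h were chosen after the calls had been seen, and the test of the 8 h models at 24 h was reworded then.

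Of the tested models, 4 had at most 3 reads over the 10 libraries of W and a mean of at least 1 CPM in BC, and 0 had the reverse with all libraries. Glyma11g12980.1 came close, with 1184 reads in W and 7 in BC, 4 of them in the outlying replicate 2 of the BC 0 h group, without which it meets the rule. The 4 models were picked after their values were seen. Glyma13g25800.1 had 2 reads in W and 944 in BC, and Glyma13g25990.1 had 3 and 417, with a mean of 2.53 CPM in BC. Glyma06g46800.1 had 0 and 215 reads, and Glyma18g47040.1 had 1 and 262. Of these 4, the 3 on chromosomes 13 and 6 lie in regions where calls cluster.

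The 83 line differences were compared with other splits of the libraries within sampling times. Of 60 splits, 2 gave at least 83 calls, the real split included, a share under 0.05. The splits do not settle whether the count arose by chance, since few were drawn and 1 other gave more calls than the real split. The other splits also mix the lines within groups, which widens their spread where the lines differ and can lower their counts. The highest other split gave 764 calls, which points to a structure of the libraries other than the line. It had the widest gap on the first principal component (75.8, against 38.5 for the real split), but 3 other splits with wider gaps than the real one (46.0, 40.4 and 39.3) gave 0 calls, so the tie to this component rests on 1 split.

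Of the 82 line differences on chromosomes, 40 lay in clusters, as donor segments in near-isogenic lines would give, and 42 did not. Some of the 42 lay on chromosome 13, whose clusters held 19, 4 and 7 of its 40 calls. Between its locus numbers 24470 and 36370 lay 39 calls, in clusters or not. Rag2 has been placed on chromosome 13 by mapping. Donor segments remain a hypothesis, since the table holds no genotypes. Random placement is argued against by the fullest window, with 13 calls where the 95th percentile at random was 3. Loss of reads in a single line at sites that differ from the reference would put nearly all cluster calls on the same side, which is argued against as the whole cause in the 4 smaller clusters, where 57.1% of 21 calls were lower in BC (exact 95% interval 34% to 78.2%), but not in the cluster with most calls, where 15.8% of 19 were (3.38% to 39.6%). Reads lost in W in that cluster, reads lost in both lines at different sites, gene copies absent from the reference and differences in transcription stay open and may all contribute.

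The peak of calls at 8 h and their absence at 24 h in edgeR was seen in both lines. Depth alone is argued against, since at equal depth the 8 h counts were 510 in W and 1446 in BC while the 24 h counts in edgeR were 0 in both (1429 and 6278 at an unadjusted p below 0.05). That the 8 h changes were as large at 24 h but hidden by spread is argued against, for the other line only, by their median there. At 24 h it was -0.0881 of that at 8 h for the calls in W and -0.438 for those in BC. Medians in the line of the call were not taken, and those in BC are set against a 0 h mean that includes its outlying replicate 2. Hidden changes of other models at 24 h stay open. In BC 6831 models (17.6%) had an unadjusted p below 0.05 and DESeq2 called 768, against 1504 (3.86%) and 58 in W. The value in BC fell strongly without replicate 2 of its 0 h group, so it depends on that library. With library weights in limma it was 1923. That fit changed the test as well and gave replicates 1 and 2 of the BC 0 h group low weights (0.286 and 0.325), so it does not single out replicate 2. Sampling time of day cannot be told apart from a short-lived response to aphids, since either could give the largest of the 4 ratios of the 24 h or 48 h change to the 8 h change, -0.0096, and no uninfested leaves at 4 h and 8 h were analysed here. The lowest ratio, for the BC calls at 48 h, was -0.638. Of these 1381 models, 24.9% at 24 h and 25.6% at 48 h kept their 8 h sign in W. Of the 594 W calls, 41.2% and 49.3% kept it in BC. The median of the BC calls thus lay past the 0 h level in W, and the reason was not tested.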
